A study of Mus musculus with 2 samples.

How the data were processed

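Whole-genome bisulfite sequencing was done on the epiblast of wild-type female C57Bl6/J embryos at embryonic day 6.5. Per the labels, 2 samples belong to this group, embryos came from natural matings and were not cultured, and the genotype was XX. Per the series' design text, the epiblast was dissected by hand, sex was determined by PCR on extraembryonic tissue, and libraries followed a published bisulfite protocol that adds adapters after conversion. Bisulfite turns unmethylated cytosine into uracil, which is read as thymine, and leaves methylated cytosine unchanged.

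The values deposited by the authors are counts of reads, with a methylated and an unmethylated count for each strand of each CpG. The submitters' processing notes name the build mm10 and the tools cutadapt 1.3, Bismark 0.12.5 and Bowtie2 2.1.0, with no role or order. The layout of the table, 43816016 lines without a header with every CpG listed whether or not it had reads, is that of a Bismark report. The columns carry no sample name. The table was taken as the pool of the group, and how the samples were combined, whether duplicate reads were removed and which filters were applied are not given in the sources used here. No count was normalized. A table without a column per sample gives no replicate error, and no p-value between groups was computed. Adapters added after conversion and repeated reads of the same fragment can change the depth at a CpG, and counts from duplicate reads narrow the intervals without adding information.

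Both strands of a CpG were added, which gave 21908008 CpGs on 66 sequences and 137691322 read counts. Sequences other than the autosomes, X, Y and mitochondrial genome held 0.134% of the read counts and were left out. The level of a region is its methylated count over its total count, in percent. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only, with each count taken as independent. Gene positions and symbols came from a RefSeq gene table of GRCm38.p6, whose chromosomes are those of mm10. All 367 list entries in 13 lists matched 1 gene each. The table gives both ends of a gene without its strand, so the promoter was the window of 500 bp on either side of the end with more CpGs. This differs from the design, which took the annotated transcript start. Where a gene's transcription starts relative to this window was not tested. Named genes measured in CpG-poor windows were Bgn, Mtm1, Piwil2, Impact, Snrpn, Ywhaz, Reep5, Gata4, Nr5a2, Dnmt3a, Elf5, Gata3, Csf1r, Cd52, Pcdhb15 and Taf1.

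A promoter was measured when it had at least 5 CpGs with a read and at least 20 read counts. Read counts are added over CpGs, so a read that spans several CpGs is counted at each. CpG-rich promoters held at least 40 CpGs in the window, CpG-poor ones under 20, and intermediate ones the rest. Chromosome comparisons used 21631 protein-coding genes, less those without a measured window. A promoter was called low when the upper bound of its interval was under 20%, intermediate when the interval lay within 20% to 60%, high when the lower bound was over 60%, and otherwise unresolved. Gene bodies left out 1000 bp at each end. CpG-dense regions were 500 bp windows in steps of 100 bp with at least 20 CpGs, merged where they overlapped.

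Gene lists were set against 10000 random lists of the same size, drawn within 5 classes of CpG number and 3 classes of reads per CpG. A percentile of 0 or 100 means that no random list lay beyond the list. Lists on the X were tested on CpG-rich members against other X promoters, and autosomal lists on all classes against autosomal promoters. Percentiles describe this table and are not p-values. Members on another chromosome than their list was meant for were left out, which removed Sohlh1 from the X germline list. A few genes are on more than 1 list, among them Jpx, Ftx, Sox17, Lefty1 and Foxd3. For position along the X, levels were shifted around the chromosome in a circle, which keeps neighbors together.

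The samples, most comparisons, gene lists, definitions and most alternatives were chosen before the data were examined. Not in that plan were the escape and silenced housekeeping lists against autosomal lists and the shuffles between those 2 lists. Nor were the number of escape genes expected among the 10 lowest X promoters and the promoter medians by CpG number. The alternatives were depth minimums, other summaries of a region, single strands, removal of CpGs above the 99.9th percentile of depth, other windows and thresholds, and unmatched lists. Added after the data were seen were overlapping promoters counted once, genes with a single CpG-dense end, CpG-rich list members alone and widened intervals. The families of multi-copy X genes were written down after the data were seen, although leaving them out was planned. The named genes follow a rule. Named were every measured member of the escape, inactivation center and imprinted lists, and the 2 highest and 2 lowest members of each other list. Also named were the 10 highest and 10 lowest X CpG-rich promoters and the 10 highest autosomal ones, passing over genes whose symbols are Gm with a number or end in Rik. The values of 2 genes that meet this rule are not reported here. Taf1, Zfx, Bex3, Nrk, Nxf3, Bex4 and Armcx6 were named after their values were seen.

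The procedure was tested on simulated data in which 200 of 10334 autosomal CpG-rich promoters were raised by a known amount. In 40 runs each, lists raised by 3, 7 or 15 points fell outside the central 95% of random lists in 100% of runs, and unchanged lists in 0%. The gene lists had 3 to 52 tested members. Lists of that size were not simulated, so this detection does not carry over to them. Simulated counts were drawn from a binomial distribution, so it was by construction that the intervals held the true level in 96.3% of promoters. Spread beyond the binomial was not simulated, so this coverage does not carry over to the data. In the data, the strands served as a repeat measurement within the table. Levels of CpG-rich promoters from the plus and minus strands correlated across promoters at r = 0.86 on the X (291 promoters, SD of the difference 5.91 points) and r = 0.76 on the autosomes (10321 promoters, SD 4.24 points). The variance between strands was 3.87 times the binomial one on the X and 4.78 times on the autosomes. The strands read different cytosines, so this ratio is not a measure of technical error alone. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.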

Results

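DNA methylation was measured across the genome in the epiblast of wild-type female C57Bl6/J mouse embryos at embryonic day 6.5. The epiblast is the layer of the early embryo that gives rise to the fetus and to the germline, and around this stage each of its female cells silences 1 of its X chromosomes. The labels list 2 samples in this group, and the counts were given as 1 table with no column per sample, so no value below has a replicate error. Comparisons were made between parts of the genome within that table. On the autosomes and the X, 89.2% of 21353092 CpGs had at least 1 read, with a median of 6 reads per CpG and 137430444 read counts in all. Intervals in parentheses are exact Clopper-Pearson 95% intervals. They cover counting error only and take each read count as independent. A single read can span several CpGs and the counts carry no molecular identifiers, so the intervals can be too narrow. Coordinates are those of mm10.

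The epiblast genome was highly methylated, at 66.3% of read counts over the autosomes and the X. CpG-rich promoters stood apart, with a median of 5.50% on the autosomes (interquartile range 3.87% to 7.87%, 10334 promoters). Promoters with intermediate CpG content on the autosomes had a median of 22.8%, and CpG-poor ones had 73.7%. A promoter here is the 1 kb window centered on the end of the gene that holds more CpGs. CpG-rich windows hold at least 40 CpGs.

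The study concerned X-linked genes, and the first comparison set the X against the autosomes by type of sequence. On the X, CpG-rich promoters were more methylated than on any autosome, whereas gene bodies and intergenic DNA were less methylated than on any autosome. CpG-rich promoters had a median of 12.5% on the X and a mean of chromosome medians of 5.50% ± 0.238 on the autosomes (SD, n = 19 autosomes, range 5.18% to 5.97%). Gene bodies of the X were at 66.2%, compared with 73.6% ± 1.03 on the autosomes, whose lowest value was 70.9%. Intergenic CpGs of the X were at 69.1%, compared with 71.9% ± 0.796, with a lowest autosome at 70.3%. Promoters of intermediate CpG content (29.8% on the X, 23.3% ± 4.52 on autosomes), CpG-poor promoters (70.2% and 73.6% ± 1.70) and all CpGs together (64.3% and 66.4% ± 1.44) lay within the range of the autosomes. Each left that range under an alternative. For all CpGs the X minus the autosomal mean was then -3.12 points as a mean of CpG fractions and -4.57 points with 1 CpG per 100 bp. It was 8.73 points for intermediate promoters when CpG-rich meant at least 60 CpGs, and -4.59 points for CpG-poor ones with windows reaching 1 kb outward. The X was less deeply covered than the autosomes, with 4.32 against 6.54 reads per CpG, and 74.4% against 89.9% of its CpGs had a read. The SD is between chromosomes, which are not replicates, so no p-value was computed.

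**Figure D1:**
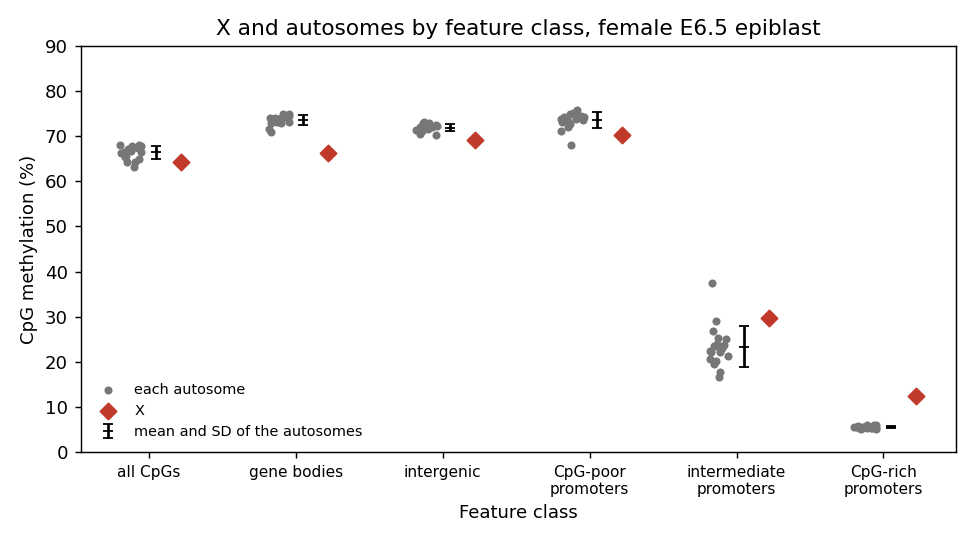
Methylation level (percent) of the X and of each of the 19 autosomes for all CpGs, gene bodies, intergenic CpGs and 3 promoter classes (medians), with the X as a red diamond, autosomes as gray points and black bars for their mean and SD. CpG-rich promoters of the X (12.5%) lie above every autosome, and gene bodies of the X (66.2%) lie below every autosome.

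Among the 295 measured CpG-rich promoters of X-linked protein-coding genes, 46 (15.6%) were at or above 20%, compared with 193 of 10334 (1.87%) on the autosomes. At or above 10% were 210 X promoters (71.2%) and 1425 autosomal ones (13.8%). The lower quartile on the X, 9.79%, lay above the upper quartile on the autosomes, 7.87%. At or above 30% were 14 X promoters, and the highest, leaving out genes with Gm or Rik symbols, were as follows. Asmt, the last enzyme of melatonin synthesis, which lies in the pseudoautosomal region, was at 79.9% (74.2% to 84.9%; chromosome X, 170677554 to 170678554). Taf9b, a subunit of the general transcription machinery, was at 71.5% (64.3% to 78.0%; chromosome X, 106220658 to 106221658). Yy2, a retroposed relative of the zinc finger gene Yy1, was at 68.3% (61.8% to 74.2%; chromosome X, 157568485 to 157569485). Nxf2, an RNA export factor of the testis, was at 67.5% (61.8% to 72.8%; chromosome X, 134964254 to 134965254). The deubiquitinase gene Otud6a was at 65.5% (60.6% to 70.04%; chromosome X, 100428408 to 100429408). The testis gene Taf7l (62.3%), the Polycomb inhibitor Ezhip (61.8%) and the meiosis gene Tex11 (54.3%) followed. Tmsb4x, which encodes a thymosin that binds actin, was methylated in 29 of 58 read counts (36.6% to 63.4%). These came from only 7 of the 42 CpGs in its window. Klhl34 was at 31.6%.

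At the other end of the X distribution, the spermine synthase gene Sms was at 3.73% (2.53% to 5.28%; chromosome X, 157491787 to 157492787), and the cohesin gene Stag2 was at 4.39% (3.33% to 5.68%; chromosome X, 42148797 to 42149797). Pdzd4 and Nudt11 (with reads at 27 of its 128 CpGs) were each at 4.98%, and Fmr1, the gene of fragile X syndrome, was at 5.76%. Of the 10 lowest, 4 were Kdm5c (5.29%), Ddx3x (5.58%), Eif2s3x (5.69%) and Utp14a (5.93%), all on the list of genes known to escape X inactivation. A random draw of 10 from the 287 X promoters without Gm or Rik symbols, 8 of which are on that list, would hold 0.279 of them on average.

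The X median was set against 10000 random lists of autosomal CpG-rich promoters of the same size, matched on CpG number and on reads per CpG. The medians of those lists averaged 6.69% (central 95% from 6.25% to 7.16%), and the highest was 7.61%, below the X median of 12.5%. Their share of promoters at or above 20% averaged 3.77% and reached at most 8.14%, below the 15.6% of the X. The excess was present at every CpG number. With 40 to 49 CpGs the X median was 14.6% and the autosomal one 9.04%, and with at least 80 CpGs they were 9.88% and 3.88%. By their intervals, 215 X promoters were low (under 20%), 9 intermediate (20% to 60%), 7 high (over 60%) and 64 unresolved, compared with 10002, 96, 24 and 212 on the autosomes. X promoters had a median of 559 read counts and an interval width of 5.72 points, and autosomal ones had 800 read counts and 3.31 points. With intervals widened to the spread seen between the DNA strands, an alternative chosen after the data were seen, 160 X promoters were called low, 3 intermediate, 1 high and 131 unresolved, compared with 9576, 57, 9 and 692 on the autosomes. The number at or above 20% was 78 when 1 CpG per 100 bp was kept and 25 with windows reaching 1 kb outward. For those wider windows CpG-rich meant at least 40 CpGs per kb. The count of 25 is therefore not out of the same 295 promoters, and its share is not given here.

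**Figure D2:**
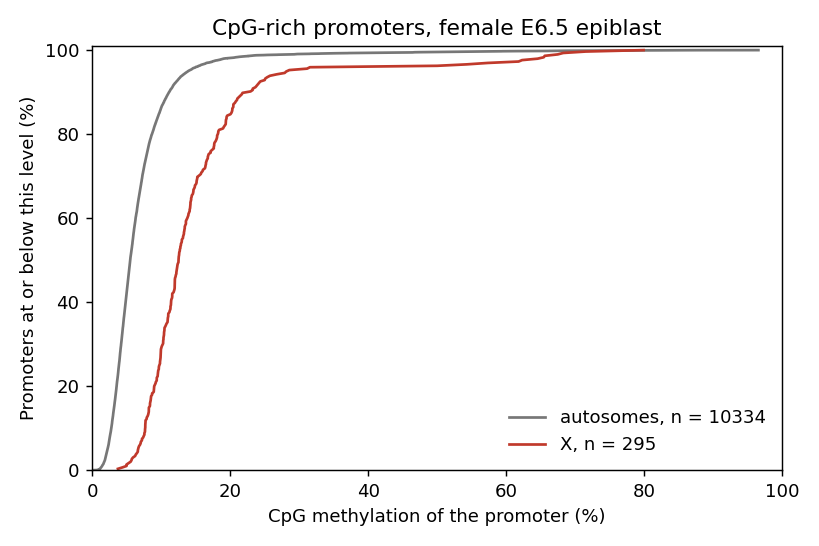
Cumulative share of CpG-rich promoters (percent, vertical axis) at or below each methylation level (percent, horizontal axis), for the X (red, 295 promoters) and the autosomes (gray, 10334 promoters). The X curve lies to the right of the autosomal one, with medians of 12.5% and 5.50%.

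Escape genes remain active on the silenced X, and their promoters were compared with other X promoters. They had the lowest median of the 4 X-linked lists, and 11 of 14 measured members were low, 1 was intermediate and 2 were unresolved. The low members included the histone demethylase gene Kdm5c (5.29%; chromosome X, 152232698 to 152233698), the RNA helicase gene Ddx3x (5.58%; chromosome X, 13279996 to 13280996) and the translation factor gene Eif2s3x (5.69%; chromosome X, 94212151 to 94213151). The others were 5530601H04Rik (5.43%), Utp14a (5.93%), Jpx (6.84%), the deubiquitinase gene Usp9x (7.73%), Pbdc1 (9.66%), Ftx (10.4%), Shroom4 (12.8%) and the Mediator gene Med14 (13.2%). Car5b (15.5%) and the noncoding gene Firre (15.9%) were unresolved, and Bgn, the proteoglycan biglycan, was intermediate at 42.6% in a CpG-poor window. Kdm6a and Mid1 fell under the depth minimum. The 9 CpG-rich members had a median of 6.84%, below all 10000 matched random lists of other X promoters, whose medians averaged 14.5% (central 95% from 10.5% to 19.5%). Against matched autosomal promoters the same 9 lay at percentile 45.0, with random lists averaging 7.17% (4.50% to 10.5%). With windows reaching 1 kb outward, the escape median was 11.4%, at percentile 1.2 of other X lists.

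X-linked housekeeping genes known to be silenced on the inactive X were mostly low, with 24 of 36 low, 3 intermediate, 0 high and 9 unresolved. Fmr1 (5.76%; chromosome X, 68678036 to 68679036) was lowest. The myotubularin gene Mtm1 was highest at 70.9%, in a window of 8 CpGs, and Bcap31 was at 52.7%. Besides Bcap31, the intermediate members were Zfx (40.7%) and Taf1 (33.3%, in a CpG-poor window), named after their values were seen. Their 25 CpG-rich members had a median of 9.95%, compared with 6.51% (5.08% to 8.24%) for matched autosomal lists, at percentile 99.89. It was 3.11 points above the escape median, at percentile 99.5 of 10000 shuffles of members between the 2 lists. That test was not planned and was run only with the main settings. With windows reaching 1 kb outward, where CpG-rich members are chosen anew, the order turned, at 11.1% for silenced and 11.4% for escape genes. With 250 bp on either side the medians were 9.01% and 7.66%. In the other alternatives with both values the silenced median stayed higher. Against other X promoters (12.7%, central 95% from 10.4% to 15.1%) the silenced housekeeping list lay at percentile 0.36. That last contrast lost its place outside the central 95% in 6 of 11 alternatives, for example with plus strand reads alone, where the median was 11.9% at percentile 35.1.

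In the X inactivation center, the region that controls silencing, the window at the higher-coordinate end of Xist was at 46.2% (37.4% to 55.1%; chromosome X, 103482733 to 103483733). Xist is the noncoding RNA that coats the silenced X. The window at the lower-coordinate end of its antisense gene Tsix was at 66.5% (58.7% to 73.6%; chromosome X, 103431017 to 103432017). The neighboring Zcchc13 was at 52.8% and the homeobox gene Cdx4 at 24.5%. Chic1 (14.6%), Rlim, a ubiquitin ligase gene that activates Xist (12.2%), Ftx (10.4%) and Jpx (6.84%) were low. The 4 CpG-rich members had a median of 13.4%, at percentile 56.6 among other X promoters.

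X-linked germline and testis genes were the most methylated X group. Of 25 measured members, 0 were low, 3 intermediate, 11 high and 11 unresolved, with a median of 68.1%. The highest were Pramel3 (86.3%; chromosome X, 135301789 to 135302789) and Magea5 (82.3%), and the lowest were Mageb16 (32.6%) and Xlr3b (46.1%), all members of multi-copy families that can share reads. Only 3 members were CpG-rich, namely Nxf2, Taf7l and Tex11, with a median of 62.3%, at percentile 99.85 of other X lists (random mean 16.4%). The other members were not set against lists matched on CpG number. X promoters as a whole had a median of 29.8% in the intermediate class and 70.2% in the CpG-poor class. The list median of 68.1% therefore depends in part on CpG content.

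**Figure D3:**
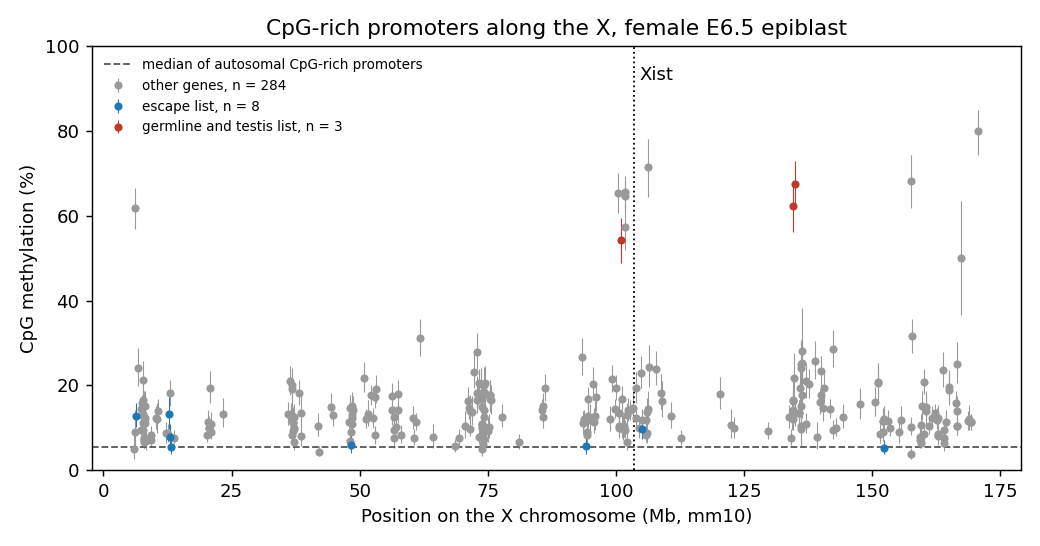
Methylation level (percent) of the 295 CpG-rich promoters of X-linked protein-coding genes against their position along chromosome X (Mb), with bars for 95% intervals, escape genes in blue, germline and testis genes in red, a dotted line at Xist and a dashed line at the autosomal median of 5.50%. The noncoding Jpx is not among these promoters, so 8 of the 9 CpG-rich escape members appear, all at or below 13.2%.

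Position was compared because silencing spreads from the Xist locus. Across the 295 promoters, level and distance from Xist gave a Spearman correlation of -0.18 (p = 0.366, two-sided, 295 circular shifts of the levels) and a Pearson correlation of -0.16 (p = 0.431 by the same permutation). The Benjamini-Hochberg adjusted p was 0.431 for both. These 2 correlations are across genes, which are not independent replicates, and neither was told apart from chance.

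Imprinted promoters that carry methylation on the maternal allele served as a scale for methylation of 1 allele. Of 15, 13 lay within 30% to 70%, and the median was 39.6%, compared with 8.88% (6.02% to 12.5%) for matched random lists. Against lists that were not matched, it lay at percentile 92.6, within the central 95%. Peg3, a zinc finger gene, was at 40.4% (36.1% to 44.9%; chromosome 7, 6729962 to 6730962), and the noncoding Kcnq1ot1, which silences its neighbors on the paternal allele, was at 36.8% (31.6% to 42.2%; chromosome 7, 143296047 to 143297047). The others within that range were Nap1l5 (50.2%), Peg13 (42.7%), Nnat (42.6%), Gnasas1 (42.1%), Airn (39.6%), Plagl1 (37.1%), Sgce (37.1%), Zrsr1 (36.7%), Peg10 (35.2%), Mcts2 (31.7%) and Snrpn (55.0% over 20 read counts in a CpG-poor window of 6 CpGs). Peg10 and Sgce share most of their windows. Mest (29.2%) lay just below, and Impact (79.6%) was measured in a CpG-poor window of 6 CpGs. H19 is not on the list of maternally methylated promoters and was measured separately. From 2 to 4 kb beyond its higher-coordinate end, the level was 39.7% (35.9% to 43.6%; chromosome 7, 142580146 to 142582146). At the same distance beyond the lower-coordinate end it was 70.5% (65.7% to 75.04%; chromosome 7, 142571530 to 142573530), and the gene table used does not say which end is the start.

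Autosomal germline genes, which are expressed in germ cells, were far above other promoters. Of 40, 5 were low, 15 intermediate, 12 high and 8 unresolved. Their median was 49.0%, compared with 9.27% (7.23% to 11.8%) for random lists matched on CpG number and reads per CpG, and it was above all 10000 of them. The testis dipeptidase gene Dpep3 was at 83.6% (79.7% to 86.9%; chromosome 8, 105978919 to 105979919), and the piRNA pathway gene Piwil2 was at 82.1% in a CpG-poor window. Boll (4.85%) and Zcwpw1 (6.41%) were lowest. Among autosomal CpG-rich promoters, leaving out genes with Gm or Rik symbols, the 10 highest included 3 of this list, Dpep3, the tubulin gene Tuba3a (78.0%) and the piRNA helicase gene Mov10l1 (68.9%). The highest of these 10 was Car5a, a mitochondrial carbonic anhydrase gene, at 84.9% (81.4% to 88.0%; chromosome 8, 121915635 to 121916635). The others were Hsd17b11 (82.1% at an end with 41 CpGs, but 11.9% at its other end with 36 CpGs), Trim52 (79.2%), the hexokinase gene Hk3 and the netrin receptor gene Unc5a (78.5% each), Arl9 (78.3%) and Tmprss12 (76.5%). The windows of Hk3 and Unc5a overlap nearly in full, so they are not separate measurements. The other end of Hk3 was at 87.3%, that of Unc5a at 41.4% and that of Car5a, with 11 CpGs, at 73.4%. Which of these ends are the starts is not known here.

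Housekeeping promoters were low in 27 of 30, with a median of 6.20%, at percentile 50.2 of matched lists. The elongation factor gene Eef2 was at 2.21% and Gapdh at 2.29%, with 26.6% at its other end. Ywhaz (86.3%) and Reep5 (82.0%) were measured at CpG-poor gene ends. Developmental regulators bound by Polycomb in stem cells were low in 43 of 46, with Hoxa13 at 2.61% (chromosome 6, 52260380 to 52261380) and Gsc at 3.52%. Tbx5 was at 20.9%, and Gata4 was at 84.1% in a CpG-poor window and at 33.1% at its other end. Their median of 7.37% lay at percentile 98.6 of matched lists (5.05% to 7.22%), but it returned within the central 95% in 6 alternatives and lay at percentile 9.52 of lists that were not matched.

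Genes of the epiblast and primitive streak were low in 19 of 24, with Lin28b at 2.38% and the embryonic chromatin factor gene Utf1 at 2.88%. Lefty2, a Nodal inhibitor, was at 58.9%, and Dnmt3a was at 76.0% in a CpG-poor window. Their median of 7.90% lay at percentile 97.8, and its direction turned in 3 alternatives, for example at 5.79% and percentile 39.2 with minus strand reads alone. Genes of naive pluripotency, an earlier state than that of the epiblast at this stage, were split. Klf5 (1.63%) and Klf4 (2.78%; chromosome 4, 55531975 to 55532975) were lowest, whereas Nr5a2 (87.6%) and Esrrb (82.6%; chromosome 12, 86521128 to 86522128) were highest. Nr5a2 was measured in a CpG-poor window, and the other end of Esrrb was at 51.3%. Of 18, 7 were low, 5 intermediate, 3 high and 3 unresolved, and the median of 29.9% lay at percentile 94.0. The 6 CpG-rich members alone, an alternative chosen after the data were seen, had a median of 4.34%.

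Markers of other tissues were included because dissection can leave neighboring cells. Extraembryonic markers had a median of 22.04% at percentile 73.3, with 7 of 23 low, 3 intermediate, 4 high and 9 unresolved. Of the 31 markers listed, 6 were left out because they are not on an autosome and 2 for depth. With windows of 250 bp on either side, the median was 13.2%, at percentile 46.3. The trophoblast gene Elf5 (85.2%) and Gata3 (76.9%), both in CpG-poor windows, were highest, although the other end of Gata3, with as many CpGs, was at 15.3%. Cdx2 (7.11%) and Sox17 (8.37%) were lowest. With CpG-rich members alone, an alternative chosen after the data were seen, 8 extraembryonic markers had a median of 12.5% at percentile 99.4. Markers of blood and maternal decidua had a median of 71.7% at percentile 79.7, with 1 of 15 low, 0 intermediate, 8 high and 6 unresolved. Csf1r (92.4%) and Cd52 (82.6%) were highest, and Coro1a (10.1%) and Spi1 (18.3%) were lowest. The other ends of Coro1a (23 CpGs) and Spi1 (13 CpGs) were at 88.9% and 78.5%, and which end is the start is not known here. Unmatched lists placed that median at percentile 99.7. Clustered protocadherins, cell surface genes of neurons, had a median of 18.9% at percentile 30.2, with 22 of 52 low, 17 intermediate, 0 high and 13 unresolved. Pcdhb15 (52 of 104 read counts) and Pcdhb13 (46.8%) were highest, and Pcdhgb6 (8.01%) and Pcdhga5 (8.31%) were lowest. Percentiles of the 13 lists describe this table and were not corrected for their number.

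**Figure D4:**
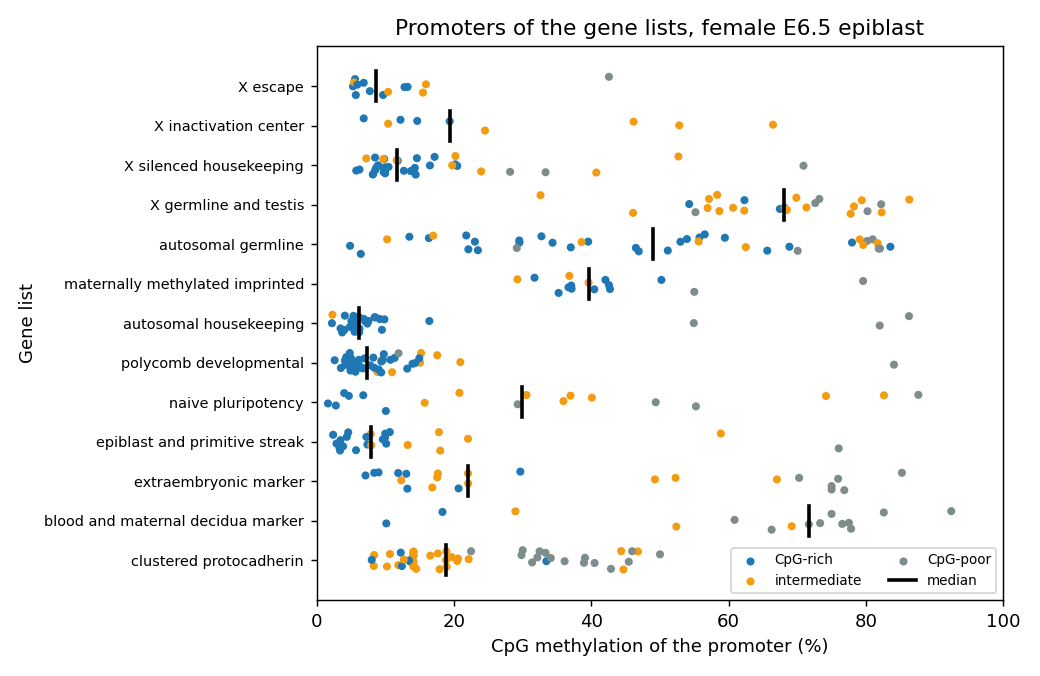
Methylation level (percent) of the measured promoters of each of the 13 gene lists, each point a promoter colored by CpG class and each bar a median. Blood and decidua markers (median 71.7%), X-linked germline genes (68.1%), autosomal germline genes (49.0%) and imprinted promoters (39.6%) lie highest, and autosomal housekeeping promoters lie low (6.20%).

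CpG-dense regions were also found from CpG positions alone, as 500 bp windows with at least 20 CpGs. At gene ends, the X regions had a median of 15.02% (482 regions) and the autosomal ones 7.18% (13716 regions, chromosome medians from 6.61% to 8.07%). The X median was above all matched autosomal lists, which averaged 8.86%. Away from gene ends, the X regions were at 78.0% (1360 regions) and the autosomal ones at 76.5% (26909 regions, chromosome medians from 69.9% to 78.6%), so the X lay within the range of the autosomes. Matched autosomal lists averaged 79.7% (78.6% to 80.7%), with the X below that mean at percentile 0.075, so that the direction turned with matching. With at least 30 CpGs per window, this last X median was 62.1%, at percentile 43.0.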

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

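The mitochondrial level, its levels by strand, the autosomal median and the depth of the Y were set beforehand as measurements, whereas the ratio of methylated counts between strands and the tests of X depth and Y-linked genes were chosen after the results were seen. Mitochondrial CpGs and the Y are outside the comparisons of the report and served as checks of conversion and mapping.

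Mitochondrial CpGs read as 45.1% methylated (44.7% to 45.5%) over 53056 read counts, although mitochondrial DNA is generally held to be little methylated. Failed conversion of all DNA is argued against by the autosomal CpG-rich promoters, whose median of 5.50% bounds the unconverted share in nuclear DNA. Methylated nuclear copies are argued against by the strands, since methylated counts on the plus strand were 1.77 times those on the minus strand, outside the nuclear range of 0.987 to 1.03. Poor conversion of mitochondrial DNA alone cannot be told apart from true methylation, because non-CpG cytosines were not analysed here, and the strand gap of 37.4 points is a value that either may give. The mitochondrial level is therefore no measure of nuclear conversion.

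The Y had 0.681% of the autosomal depth in these female samples, above the level that 0 reads would allow. It was 0.393% without CpGs of extreme depth. Of its 22885 read counts, 66.9% lay beyond 90 Mb.

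The X had 66.0% of the autosomal depth, although female cells carry the same number of copies of each. Sequence that cannot be mapped uniquely may lower the overall depth, but at CpG-rich promoters the X still had 86.0% of the autosomal reads per CpG, below each of the autosomes. Male cells in the sample are argued against by 5 Y-linked genes, at 1.23% of autosomal gene depth where 14.0% would be needed to account for the gap at promoters. Late replication of the silenced X, or loss of an X in part of the cells, stays open and cannot be told apart here, since the depth of 85.7% at promoters with at least 80 CpGs fits either and no sorted phases or single cells were analysed here. How composition and library preparation act on depth was not tested.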

How the results depend on the processing

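Most alternatives were set beforehand, and CpG-rich list members alone, widened intervals, overlapping promoters counted once and genes with a single CpG-dense end were chosen after the data were seen. No paired analysis was possible because the samples share 1 table without a column per sample. The planned use of the 5 prime end of each gene was not run, since the gene table gives no strand, and windows of 1 kb upstream became 1 kb outward. With at least 60 CpGs, the escape and X germline lists had too few members for a value, as had the X germline list with windows 1 kb outward. The X median of CpG-rich promoters stayed above the central 95% of random lists in all 14 alternatives (10.4% to 15.1%). The same held for the autosomal germline list in all 11 (38.3% to 54.1%) and, on the low side, for the escape list in all 11 (6.83% to 11.4%). Of 871 values of named promoters under alternatives, 738 stayed within their interval and 133 moved out of it. At this depth, X CpG-rich promoters had a median interval width of 5.72 points, which limits single promoters.

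Where a result changed, the cause was not tested, except that fewer promoters qualify at a higher threshold and fewer counts at a larger divisor. The genome-wide level was 68.9% as a mean of CpG fractions, 72.0% with 1 CpG per 100 bp, 66.2% on the plus strand, 66.4% on the minus strand and 66.4% without extreme depth. The Y depth was 0.707%, 0.653% and 0.393% for the plus strand, minus strand and no extreme depth, and the mitochondrial level was 66.2%, 28.8% and 42.1%. For all CpGs, the X minus the autosomal mean was -3.12 points by CpG fractions and -4.57 points with 1 CpG per 100 bp, both beyond the range of the autosomes. The same difference was 8.73 points for intermediate promoters when CpG-rich meant at least 60 CpGs, and -4.59 points for CpG-poor promoters with windows 1 kb outward. The number of methylated X promoters was 78 with 1 CpG per 100 bp, 25 with 1 kb outward, 9 at 60 CpGs or more, 210 at a level of 10% and 14 at 30%. The 25 and the 9 come from CpG-rich classes formed anew and not from the same 295 promoters, and their shares are not given here. With widened intervals, 3 X promoters were intermediate and 1 high. The X median of CpG-dense regions away from gene ends, at 30 CpGs per 500 bp, was 62.1%.

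The silenced X housekeeping list returned within other X lists at 11.2% (CpG fractions), 13.0% (1 CpG per 100 bp), 11.9% (plus strand), 10.3% (minus strand), 11.1% (1 kb outward) and 8.73% (at least 60 CpGs). Polycomb targets returned within random lists at 8.84% (1 CpG per 100 bp), 6.96% (plus strand), 7.26% (minus strand), 7.40% (250 bp), 8.78% (1 kb outward) and 6.13% (CpG-rich members), and turned direction against unmatched lists at 7.37%, within their central 95%. The epiblast list returned at 9.26% (1 CpG per 100 bp), 8.23% (1 kb outward) and 5.16% (CpG-rich members), and turned direction at 5.79% (minus strand), 5.12% (250 bp) and 7.90% (unmatched). Blood and decidua markers passed out of random lists at 76.0% (minus strand) and 71.7% (unmatched), and extraembryonic markers at 12.5% (CpG-rich members). Imprinted promoters returned within unmatched lists, at 39.6%.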

Other observations

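Matching on depth and CpG number and leaving out multi-copy families were set beforehand. The escape genes, silenced housekeeping genes and other X promoters against autosomal lists were tests chosen after the results were seen. So were the shuffles between the escape and housekeeping lists, the shuffles along the X and the counts by list and family. Of 120 autosomal CpG-rich promoters called intermediate or high, 17 were on the germline list, 8 on the imprinted list, 1 on the extraembryonic list and 1 on the protocadherin list, and 93 were on none of the lists. With intervals widened to the spread between strands, 57 autosomal CpG-rich promoters were intermediate and 9 high. Of the 46 X promoters at or above 20%, 7 belonged to multi-copy families and 4 to genes with Gm or Rik symbols.

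The excess of methylation at CpG-rich promoters of the X was weighed against technical sources. Lower depth or CpG number on the X is argued against by matched autosomal lists, above whose mean the X median lay by 5.83 points. Reads shared between multi-copy genes are argued against by the X median of 12.4% without those families, above the highest matched autosomal list. Methylation of the silenced X may account for the excess. Escape genes had a median of 6.84%, within the central 95% of matched autosomal lists (4.50% to 10.5%). The 287 X promoters outside that list had 12.5%, above all matched autosomal lists of their own size (central 95% from 6.25% to 7.17%). The range for 9 escape members is wide and also holds the silenced housekeeping median of 9.95%, so lying within it does not separate escape from silenced genes. The housekeeping list, too, lay below other X promoters, at percentile 0.36, though not in every alternative. It was 3.11 points above the escape median, at percentile 99.5 of shuffles. With windows reaching 1 kb outward this order turned, at 11.1% for silenced housekeeping and 11.4% for escape genes. Methylation of the silenced X as the source is a hypothesis, found and tested on the same data. The active and silenced X cannot be separated in these counts, and the gene ends used are not all transcript starts.

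The bin from 130 to 140 Mb of the X had the highest median of the 12 bins with at least 10 CpG-rich promoters, 16.2% over 28 promoters against 12.2% elsewhere on the X. Its 10 promoters at or above 20% include Nxf2 (67.5%), Taf7l (62.3%), Bex3 (28.1%), Nrk (25.8%), Nxf3 (64 of 256 read counts), Bex4 (24.0%) and Armcx6 (21.7%). Against matched lists of other X promoters the bin lay at percentile 99.99, which does not allow for its choice as the highest bin. A regional difference cannot be told apart from chance, since 22.3% of 10000 shuffles of the levels among X promoters gave a bin with as high a median. Bins held 10 to 41 promoters, and medians of small bins vary more, which makes the shuffles less sensitive to a bin of 28.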
